A study of Mus musculus with 6 samples.

How the data were processed

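The series measured RNA and surface proteins of single CD11b+ cells from brains of C57BL/6 mice aged 12 weeks by CITE-seq, in which antibodies carrying DNA barcodes are read together with the transcripts of each cell. CD11b is an integrin subunit of myeloid cells. Per the labels, 3 pools were each made from 6 samples marked with hashtag antibodies, namely 1 female and 1 male sample without tumor, 1 of each sex at day 14 after tumor implantation and 1 of each sex at day 21. Each pool gave 2 libraries, of mRNA and of antibody tags, so that 6 deposited libraries hold 18 hashed samples in 6 groups of 3. The brains were perfused with cold saline to remove blood cells and were dissociated with enzymes, per the labels' protocols, and libraries were made with droplet-based 3' chemistry.

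The deposited matrices held UMI counts, that is counts of distinct molecules, per gene or antibody tag and cell barcode, with no normalization by the authors. Only barcodes passing the authors' cell filter were in the matrices. The submitters' processing notes name Cell Ranger 3.0.1 and 4.0.0, bcl2fastq 2.20.0.422, Seurat version 3 and the mouse genome build mm10, while the file headers give version 3.1.0 for pool 1 and 4.0.0 for pools 2 and 3. Which step Seurat served is not given in the sources used here. The genes of the pools were joined by their Ensembl identifiers, and 30406 were listed in all 3 pools.

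The deposited feature names call the hashtags only Hashtag1 to Hashtag6, and nothing in the labels says which sample each marked. No hashtag was therefore given a sex, a tumor or a day, and the comparisons of sex, tumor and time named in the study's design were not run. The hashed samples are named by pool and hashtag number, and a number shared by 2 pools is not taken to mark the same group. The comparisons made instead lie within hashed samples, each of which gives both arms. The labels do not say which animals the samples came from. The p-values therefore measure the spread of within-sample differences over these samples, which may be partly technical. Together the hashed samples mix all groups of the study. Comparisons that use monocyte- and macrophage-like cells as a class drew only on samples under hashtags 3 to 6, so they may not cover every group. Pools served as replicates 1 to 3 in the runs that leave out 1 replicate. The counts of the pools differed far beyond sampling noise, with chi-square per degree of freedom from 98.1 to 242 over 15089 genes, so no library appeared as a repeat of another.

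Barcodes were kept with at least 200 genes, at least 500 UMIs and under 10% mitochondrial UMIs, which left 13766 of 13925 in pool 1, 10688 of 11010 in pool 2 and 11760 of 11820 in pool 3. Hashtags were assigned within each pool by the HTODemux procedure, with k-means on centred log ratios and the 0.99 quantile of a negative binomial fitted to the background. Barcodes positive for exactly 1 hashtag were used, 11577 in pool 1 (84.1%), 9229 in pool 2 (86.3%) and 4735 in pool 3 (40.3%). This removes doublets of differently hashed samples only. The automatic Scrublet threshold called almost no doublets in pools 1 and 3, so a Scrublet score limit of 0.2, set after the scores were seen, was used as an alternative. Counts were scaled to 10000 per cell and log transformed, 2000 variable genes without Xist and Y-linked genes were centred and scaled within pool, and Leiden clustering at resolution 1 on 15 neighbours in 30 principal components gave 23 clusters (scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9). Clusters were named from fixed marker lists. The first way of scoring the markers gave names that went against leading genes, and the one used here was written after those names were seen. A name needed at least 3 markers detected in 10% of cells, and a cluster led by genes of another type stayed unnamed. The 8 microglia-like clusters and the 4 monocyte- or macrophage-like clusters formed the 2 classes compared.

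Protein levels are centred log ratios, the natural log of a tag count plus 1 minus the mean of these logs over the 10 protein tags that the pools share. This scale sets each tag against the other tags of the same cell. Within a class and hashed sample, cells in the highest and lowest 25% of a tag formed a high and a low gate. For CD49d, the gates were the 2 components of a Gaussian mixture fitted to all cells of a pool. In pools 1 and 3 the component of a cell did not always rise with its CD49d level, so a single level per pool where the components cross was added as an alternative after seeing the data. RNA counts were summed per hashed sample and gate where both gates held at least 20 cells, and tested with edgeR 4.0.16 (quasi-likelihood, TMM scaling, filterByExpr, hashed sample as a block), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Adjusted p-values of genes are from that test throughout. The dependence of the CD74 effect on cell class was tested as an interaction over samples with all 4 arms. Protein differences between classes were tested by two-sided permutation of signs within hashed samples with 100000 resamples (exact below 10 pairs), adjusted over 10 proteins. Shares of cells carry exact Clopper-Pearson 95% intervals, which cover counting error only.

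Gene lists were tested with camera (limma 3.58.1) at an inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. They covered MHC class I and II, interferon response, homeostatic and disease-associated microglia, chemokines and cytokines, immune checkpoints, hypoxia, complement and phagocytosis, cell cycle, monocyte genes, lysosome and lipid handling, genes induced by dissociation, and genes of other cell types that the sort could hold. Some genes stand on more than 1 list, Cd74 being a member of MHC class II and several lysosomal genes being shared with disease-associated microglia. The genes named in each comparison were first the 8 largest rises and 8 largest falls among genes past the threshold. These needed an average log2 CPM of at least 5 and the same direction in at least 80% of samples. The coding gene of the gated protein came next, then the 3 members with the smallest p of lists called by camera. Lists were taken in order of their p and naming stopped at 30 genes, so lists with a larger p may give fewer members or none. Of the genes this rule names, 1 is not reported here. For CD49d, Tmem119, P2ry12, Ly6c2, Cd74, H2-Aa and Cd274 were named in addition, ahead of the list members and within the 30. The class I, Ly6 and interferon-induced families hold near-identical copies, and how the authors' counting divided reads between copies is not given in the sources used here.

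The fits were tested on simulated counts made from these samples. Of genes simulated with a 2-fold change, 91.0% were called in the CD74 and TMEM119 designs of microglia-like cells, 95.5%, 91.0% and 86.6% in the CD74, Ly-6C and CD274 designs of the other class, 97.0% in the CD49d design and 47.8% in the interaction design. Of 1.5-fold changes, 61.2% and 64.2% were called in the CD74 and TMEM119 designs of microglia-like cells, 47.8%, 50.7% and 44.8% in the CD74, Ly-6C and CD274 designs of the other class, 67.2% in the CD49d design and 8.96% in the interaction design. These counts were drawn with a dispersion of 0.05 for every gene, which was set and not estimated from the data, and with the same change in every sample. Genes that vary more between samples would be called less often, so these shares may overstate what the real fits recover. The groups, gates, tests, gene lists, naming rule for genes and alternatives were set before the data were examined, apart from the exceptions named here. Alternatives tried were DESeq2 1.42.0, library size scaling without TMM, no low-count filter, no block, counts summed per pool, each pool left out, at least 50 cells per gate, a 5% mitochondrial limit, a majority rule in which 1 hashtag holds 80% of hashtag UMIs, the Scrublet limit, gates by raw tag counts, gates at the median, cells thinned to 2000 RNA UMIs, Leiden resolutions of 0.5 and 2, and other protein scales. Gates restricted to macrophage-like clusters and a log2 scale of raw tag counts were added after seeing the data.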

Results

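RNA and 10 shared surface proteins were measured in single CD11b+ brain cells from 3 pools of 6 hashed samples, drawn from female and male mice without tumor or at day 14 or 21 after glioma implantation. The mRNA libraries held 74848339 UMIs in 13925 barcodes of pool 1, 107880924 in 11010 of pool 2 and 71510276 in 11820 of pool 3. The median barcode carried 4451 UMIs from 1697 genes in pool 1, 8129 UMIs in pool 2 and 4689 in pool 3. Antibody tags numbered 74364387, 93444593 and 79229502 UMIs, without the hashtags. After filtering and hashtag assignment 25541 cells remained. Because the deposited names do not say which group a hashtag marked, values are given for each hashed sample, and the comparisons ask whether a difference between cells of the same sample held across samples.

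The largest class was microglia-like cells, the resident macrophages of the brain, marked by Tmem119, P2ry12 and Sall1. They numbered 12627 in 8 clusters. Monocyte-like cells (2339), with Ly6c2 and Plac8, and macrophage-like cells of infiltrating type (5359), with Gpnmb, Ms4a7 and Arg1 among the markers, filled 4 further clusters. Hashtags 1 and 2 marked almost only microglia-like cells in each pool. In pool 1 these made up 97.9% (95% interval 97.2 to 98.5) of 1947 cells with hashtag 1 and 97.9% (97.2 to 98.4) of 2195 with hashtag 2. In pool 2 the shares were 95.9% (94.7 to 97.0) and 95.6% (94.4 to 96.6), and in pool 3 they were 94.8% (91.1 to 97.3) and 96.0% (92.8 to 98.1).

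Monocyte- and macrophage-like cells were 0 to 0.568% of cells under hashtags 1 and 2 and a large part of the cells under hashtags 3 to 6 in pools 1 and 2. In pool 1 they were 38.3% (36.1 to 40.5), 45.1% (42.8 to 47.3), 57.5% (55.2 to 59.7) and 53.4% (51.0 to 55.8) under hashtags 3, 4, 5 and 6, beside 51.7%, 37.3%, 27.7% and 33.7% microglia-like cells. In pool 2 they were 40.5% (38.0 to 43.0), 49.1% (46.8 to 51.4), 54.8% (52.3 to 57.2) and 64.6% (62.2 to 66.9), beside 45.5%, 37.6%, 28.1% and 25.1% microglia-like cells. In pool 3 they were 9.90% (6.73 to 13.9), 3.39% (2.80 to 4.08), 63.9% (58.3 to 69.1) and 77.1% (72.7 to 81.2), beside 82.9%, 6.26%, 17.1% and 3.27% microglia-like cells. The pool 3 shares depended on how hashtags were assigned. Under the majority rule, with cells clustered anew, the highest monocyte- and macrophage-like share in any sample of the pools was 64.9%. The lowest microglia-like share was then 17.7%. In pool 3, 88.6% (87.4 to 89.6) of the 3241 cells assigned to hashtag 4 fell into a cluster that stayed unnamed, because S100a9, Pf4 and S100a8, genes of neutrophils and border macrophages, led it together. That cluster took 2908 of its 2967 cells from pool 3. None of its cells entered a gate, but they were among the cells to which the CD49d mixture of pool 3 was fitted. The microglia-like clusters were also unevenly drawn from the pools, 1 of them having 2648 of 2974 cells from pool 1, another 1019 of 1135 from pool 2 and 1 more 763 of 771 from pool 3.

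**Figure D1:**
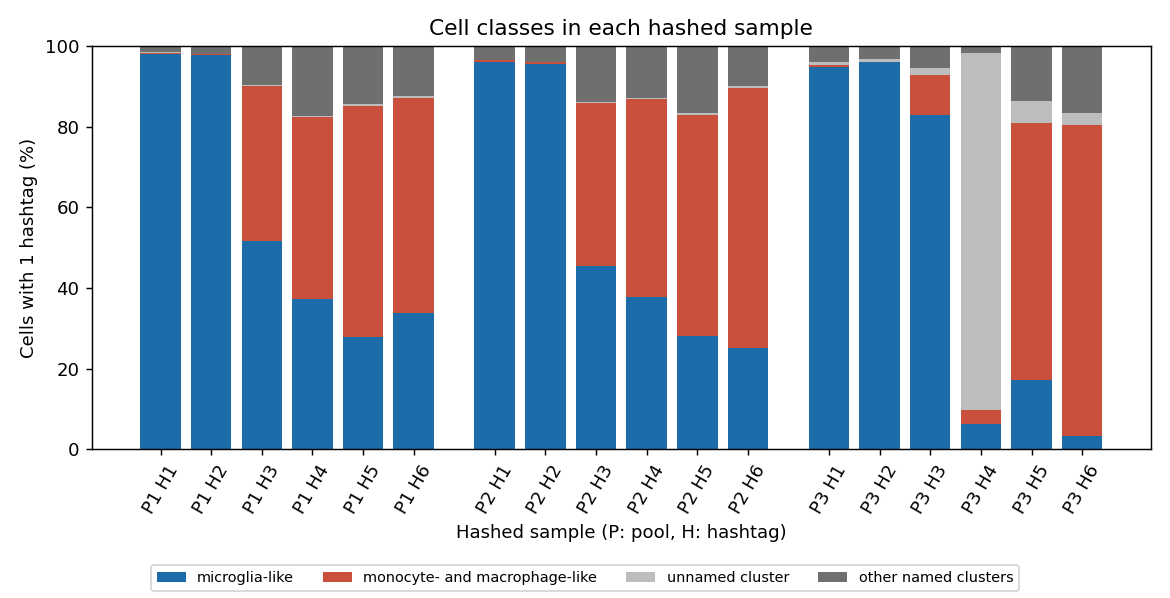
Stacked bars of the share of cells in percent (vertical axis) in each of the 18 hashed samples (horizontal axis, P for pool and H for hashtag), by cell class. Bars under hashtags 1 and 2 are microglia-like for 94.8 to 97.9% of cells in all pools, and hashtag 4 of pool 3 is 88.6% unnamed cells.

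Barcodes of pool 3 often carried mixed RNA. In 83.9% of them (9872) no hashtag reached 80% of hashtag UMIs, against 20.8% in pool 1 and 12.5% in pool 2. Of these barcodes 80.2% held both P2ry12, a microglial transcript, and Ly6c2, a monocyte transcript, and 69.7% held Gzma, a protease gene of NK cells. In pool 3 barcodes with a majority hashtag, 16.7% held both and 8.63% held Gzma, at median depths of 4421.5 UMIs without and 6279 with a majority hashtag. The chi-square per degree of freedom of a barcode against the mean profile of its set, over 300 genes, had a median of 1.14 without a majority hashtag and 8.08 with one. Of the 4735 pool 3 barcodes positive for exactly 1 hashtag, 1608 held that hashtag by majority, and among cells assigned by majority the unnamed share was at most 0.833% of a sample.

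**Figure D2:**
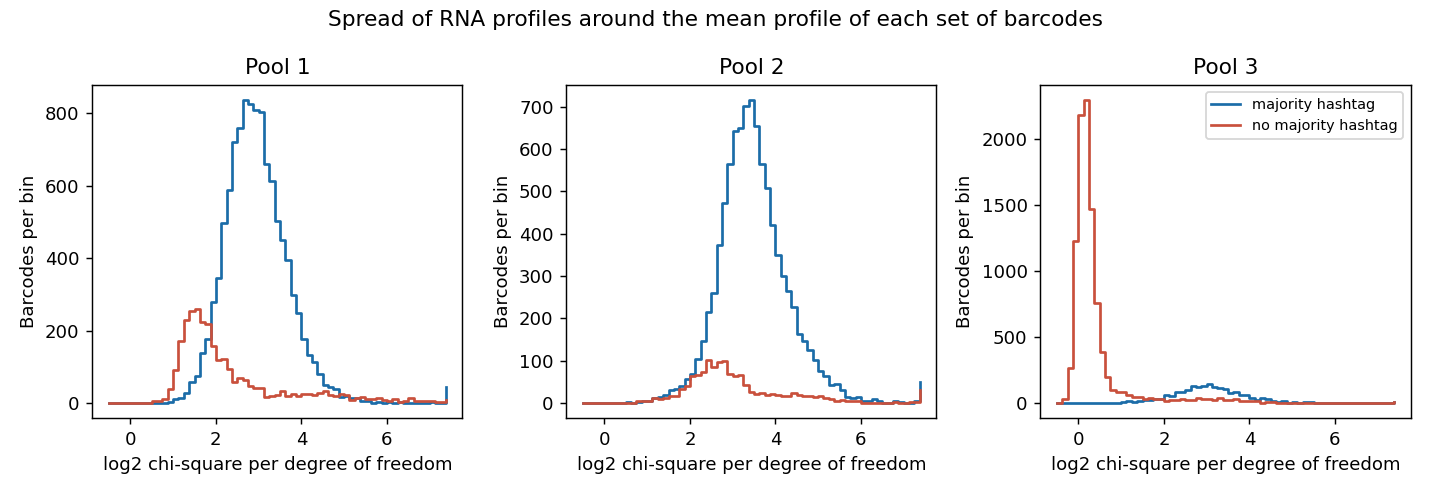
Number of barcodes per bin (vertical axis) by log2 chi-square per degree of freedom against the mean RNA profile of their set (horizontal axis), in each pool, for barcodes with and without a hashtag holding 80% of hashtag UMIs; the last bin holds all larger values. In pool 3, barcodes without a majority hashtag peak near 0, with a median ratio of 1.14, and lie apart from the others, at 8.08.

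Surface proteins separated the 2 classes that had been set by RNA alone. TMEM119, a membrane protein of microglia, was lower on monocyte- and macrophage-like cells than on microglia-like cells of the same sample by a mean centred log ratio of -2.78 (range -3.50 to -2.24, lower in 11 of 11 samples). Ly-6C, a glycoprotein of inflammatory monocytes, was higher by 1.17 (0.66 to 1.75, 11 of 11). CD49d, the integrin alpha 4 chain of blood-derived leukocytes, was higher by 0.74 (0.34 to 1.16, 11 of 11), and CD45, the leukocyte tyrosine phosphatase, by 0.72 (0.42 to 1.29, 11 of 11). The difference for CD11b was -0.83 (-1.25 to -0.53, lower in 11 of 11) and for CD74, the invariant chain of MHC class II, -0.38 (-0.79 to -0.04, lower in 11 of 11).

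Gr-1, an epitope of Ly-6G and Ly-6C, was higher by 0.41 (0.06 to 0.83, 11 of 11) and the immune checkpoint ligand PD-L1 (CD274) by 0.53 (-0.03 to 0.89, higher in 10 of 11). CD52, a small glycoprotein of leukocytes, was higher by 0.24 (-0.21 to 0.60, 8 of 11) at an adjusted p of 0.023. It did not pass the sign permutation test without pool 1 (difference 0.20, adjusted p = 0.19) or without pool 3 (difference 0.22, adjusted p = 0.078). MHC class II protein differed by 0.19 (-0.60 to 1.02, higher in 6 of 11) and did not pass the test (adjusted p = 0.26), but passed in opposite directions on the other scales, as 2.73 on log2 raw tag counts (higher in 11 of 11, adjusted p = 0.0011) and -0.53 on log2 counts per 1000 tags (lower in 9 of 11, adjusted p = 0.020). The adjusted p of the sign permutation test was 0.0015 for the remaining proteins except PD-L1 (0.0027), where the smallest raw p that 11 pairs allow is 9.8e-04. The scale mattered for most proteins. On log2 raw tag counts CD11b and CD74 turned to higher values, 1.26 and 1.92, and on log2 counts per 1000 tags the differences of Gr-1 (-0.26), PD-L1 (-0.03) and CD52 (-0.04) were also negative, CD45 (0.18, higher in 7 of 11) and CD49d (0.23, higher in 8 of 11) did not pass, and 5 proteins passed. TMEM119 and Ly-6C kept direction and call on all 3 scales.

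**Figure D3:**
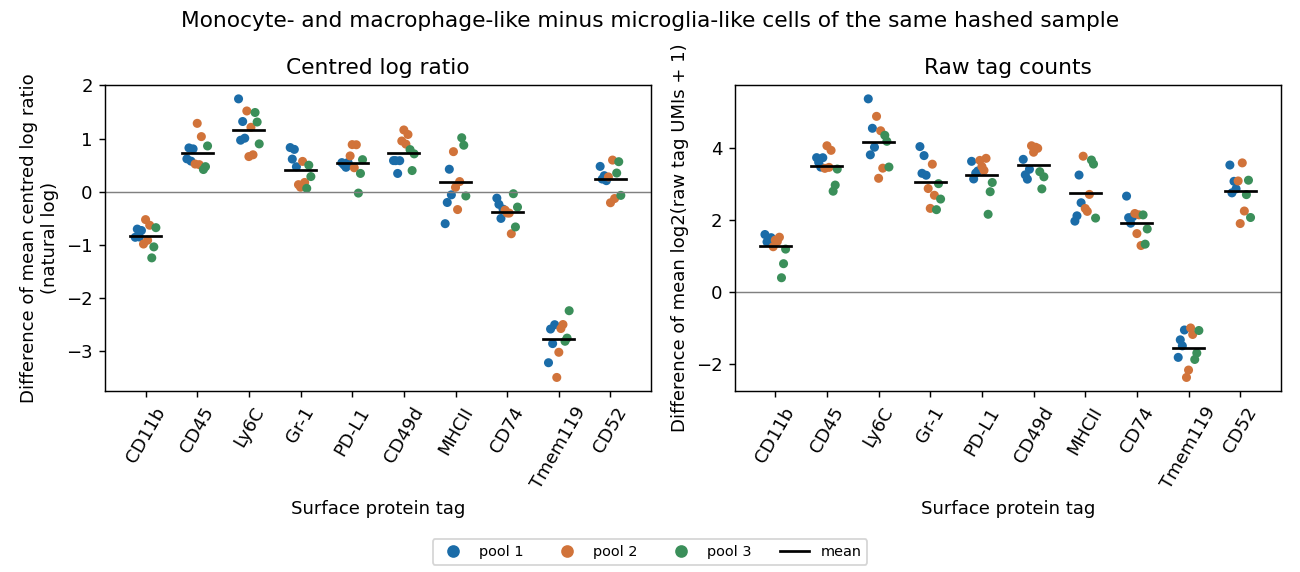
Differences of class means, monocyte- and macrophage-like minus microglia-like cells of a hashed sample, for 10 surface proteins (horizontal axis), as centred log ratio in natural log units (left, vertical axis) and as log2 of raw tag counts plus 1 (right, vertical axis). Each point is 1 of 11 hashed samples, coloured by pool, and bars are means; TMEM119 is below 0 on both scales, while CD11b and CD74 lie below 0 on the left (-0.83 and -0.38) and above 0 on the right (1.26 and 1.92).

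Microglia-like cells rich in TMEM119 protein held more RNA of homeostatic microglia genes and less RNA of inflammatory and interferon-induced genes than cells of the same sample poor in it. Its coding gene Tmem119 was 1.87-fold higher (log2 fold change 0.90 ± 0.13, SE, higher in 16 of 16 samples, adjusted p = 6.8e-06). P2ry12, a purinergic receptor through which resting microglia sense ATP, rose by 1.36 ± 0.21 on the log2 scale, P2ry13 by 1.04 ± 0.13 and the fractalkine receptor gene Cx3cr1 by 0.84 ± 0.12, each in 16 of 16 samples. Spp1, which encodes osteopontin, had a log2 fold change of -5.43 ± 0.62, and Cst7, a cystatin of activated microglia, of -4.13 ± 0.31. The interferon-induced chemokines Cxcl9 and Cxcl10 changed by -4.22 ± 0.54 and -3.52 ± 0.34. In all, 3691 of 7499 genes passed the test, 1823 higher and 1868 lower in the TMEM119-high gate.

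Each list is given with its members past the test among those measured and, in brackets, the same count adjusted over the list alone. Homeostatic microglia genes were higher in 16 of 16 (16, median log2 fold change 0.82), with Slc2a5, a fructose transporter, at 1.36. Interferon response genes were lower in 19 of 19 (19 adjusted over the list alone, median -1.63), among them Rsad2 (-3.02), Ifit1 (-1.97) and Ifit2 (-1.74). Of disease-associated microglia genes 14 of 16 were lower and 1 higher (15 and 1 adjusted over the list alone), with the receptor kinase Axl at -3.25 and the integrin gene Itgax at -2.48. Chemokines and cytokines were lower in 14 of 18 and higher in 2 (15 and 2 adjusted over the list alone), including Ccl3 (-1.25), Cxcl2 (-2.24) and the interleukin gene Il1a (-1.37). MHC class I genes were lower in 11 of 12 (11 adjusted over the list alone), with B2m, the light chain, at -0.82, and MHC class II genes in 6 of 8 (6). Hypoxia genes were lower in 9 of 10 (10 adjusted over the list alone), lysosome and lipid genes in 10 of 14 (10), monocyte genes in 4 of 5 (5), and complement genes in 9 of 15 with 1 higher (12 and 1). Camera called these 10 lists, and no call held with an estimated correlation (adjusted p = 0.13 to 0.18).

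Other strong falls were in Cybb, the NADPH oxidase subunit (-3.77), Lgals3 (-3.62), which encodes galectin-3, Cd72 (-3.50) and Bcl2a1d (-3.49), a relative of the survival factor Bcl2. Il7r (1.62), Csmd3 (1.51), the transcription factor gene Sox4 (1.47), Upk1b (1.35), Bank1 (1.33) and Lrba (1.32) were among the largest rises. Scaling by library size alone put the median of all genes at 0.27 and moved the split to 3621 higher and 990 lower, with no named gene changing direction. Without pool 2, 2063 genes passed. The other tags were lower in the TMEM119-high gate in 16 of 16 samples. With raw-count gates interferon response genes were lower in 13 of 19 (median -0.81) and MHC class II genes in 4 of 8 with 1 higher (median -0.22, against -0.78). MHC class I genes were then lower in 7 of 12 (median -0.26, against -0.61). Dissociation-induced genes were lower in 3 of 15 and higher in 2 (median -0.13) in the gates by centred log ratio and lower in 9 with 1 higher (median -0.39) in raw-count gates, and the median mitochondrial share was 1.497% in the high and 2.09% in the low gate.

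Microglia-like cells in which CD74 protein was high relative to the other tags had less RNA of activation genes and of antigen presentation than cells where it was low, and this direction turned when gates were set on raw CD74 counts. The CD74 tag was sparse on microglia-like cells, with medians of 8, 6 and 5 UMIs in pools 1 to 3. On NK cell-like cells the medians were 3, 2 and 2. Whether the gates separate CD74 protein from background binding was not tested. Cd74 itself was lower, with a log2 fold change of -0.73 ± 0.13 (SE, lower in 14 of 16 samples, adjusted p = 2.3e-04), but higher by 0.42 ± 0.098 with raw gates (adjusted p = 0.0021). Cxcl9 had a log2 fold change of -2.11 ± 0.30, Lgals3 of -1.76 ± 0.19, Fabp5, a fatty acid binding protein gene, of -1.64 ± 0.22 and the intermediate filament gene Vim of -1.25 ± 0.20, where raw gates gave 0.83, 1.01, 1.38 and 1.32. The rises were small, Serpinf1 at 0.49, Sox4 at 0.42 and Arhgap45 at 0.37, and Sox4 turned to -0.42 with raw gates. Of 7728 genes 1018 passed, 259 higher and 759 lower. Among 1012 of them also present with raw gates, 908 had the opposite sign and 550 passed in the opposite direction, against 5 that passed in the same one.

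In these gates MHC class II genes were lower in 7 of 8 (7 adjusted over the list alone), with H2-Aa at -0.83 and H2-Eb1 at -0.78, and MHC class I genes in 6 of 12 (8). Interferon response genes were lower in 10 of 19 (13 adjusted over the list alone), including the GTPase gene Gbp2 (-0.86) and Ifitm3 (-0.72). Disease-associated microglia genes were lower in 11 of 16 (12), chemokines and cytokines in 9 of 18 (11), hypoxia genes in 7 of 10 (7), complement genes in 7 of 16 (8), monocyte genes in 4 of 5 (4) and lysosome and lipid genes in 8 of 15 (9), with the scavenger receptor gene Cd36 at -1.27. Homeostatic microglia genes were higher in 13 of 16 (15 adjusted over the list alone), Selplg by 0.34 and P2ry13 by 0.30. Camera called these 10 lists, none with an estimated correlation (adjusted p = 0.097 to 0.13), and each of them was called in the opposite direction with raw gates. Dissociation-induced genes, 1 higher and 1 lower of 15 in these gates, were lower in 13 of 15 with raw gates (median -0.34). Scaling by library size alone gave 807 higher and 353 lower genes. The count was 250 without pool 1, 89 without pool 2 (where 11 of the named genes no longer passed), 512 with counts summed per pool and 1 with no block for the sample.

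Among monocyte- and macrophage-like cells, those rich in Ly-6C protein carried more RNA of monocyte and interferon-induced genes than those poor in it. Ly6c2, a coding gene of Ly-6C, was 14.1-fold higher (log2 fold change 3.82 ± 0.33, SE, 11 of 11 samples, adjusted p = 3.7e-08). Chil3, a chitinase-like protein gene of monocytes and macrophages, was 15.9-fold higher (3.99 ± 0.43), and Vcan, which encodes the proteoglycan versican, 20.1-fold (4.33 ± 0.27). The macrophage elastase gene Mmp12 had a log2 fold change of -4.14 ± 0.36 and the complement genes C1qa and C1qc of -2.23 ± 0.22 and -1.97 ± 0.18, each lower in 11 of 11 samples. Of 7672 genes 3767 passed, 1992 higher and 1775 lower in the Ly-6C-high gate.

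All 13 tested monocyte genes were higher (13 adjusted over the list alone, median log2 fold change 3.13), among them Plac8 (3.52), and so were 19 of 19 interferon response genes (19, median 1.54), with Ifit3 at 2.30, Isg15 at 1.96 and Usp18 at 1.54. MHC class I genes were higher in 9 of 12 (9 adjusted over the list alone), including the peptide transporter gene Tap1 (0.66) and the class I regulator Nlrc5 (0.82), whereas MHC class II genes were lower in 6 of 9 (6), H2-Ab1 by -1.42. Disease-associated microglia genes were lower in 12 of 17 with 1 higher (12 and 2 adjusted over the list alone), with the lipid receptor gene Trem2 at -1.21 and the tetraspanin gene Cd63 at -1.30. Hypoxia genes were higher in 10 of 14 and lower in 2 (10 and 2). Genes induced by tissue dissociation were higher in 11 of 15 and lower in 1 (12 and 2 adjusted over the list alone), with Atf3 at 0.84 and Junb at 0.64. None of these 7 camera calls held with an estimated correlation (adjusted p = 0.19 to 0.35). The chemokines Ccl8 (-3.58) and Pf4 (-2.85) were among the other falls, and Ifitm6 (3.83) and Hp (3.13) among the rises.

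Monocyte-like clusters made up a median over samples of 63.9% of the Ly-6C-high gate and 9.81% of the low gate. Within macrophage-like clusters alone, gates added after seeing the data, 1759 genes passed, with interferon response genes higher in 18 of 19 (median 0.72 against 1.54), monocyte genes in 11 of 12 (1.71 against 3.13) and MHC class II genes lower in 5 of 9 (-0.35 against -0.999). Disease-associated microglia genes were there lower in 5 of 15 and higher in 1 (-0.11 against -0.58). Dissociation-induced genes were there higher in 11 of 15 and lower in 1 (0.43 against 0.48). Raw-count gates gave 2433 genes, with interferon response genes higher in 19 of 19 (median 0.97), monocyte genes in 12 of 13 (2.16) and MHC class II genes lower in 5 of 9 (-0.35). Library size scaling gave 1605 higher and 2276 lower.

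Cells of this class with high PD-L1 protein carried less RNA of monocyte and interferon-induced genes than cells with low PD-L1. Cd274, which encodes PD-L1, differed by 0.21 ± 0.12 on the log2 scale (higher in 8 of 11 samples) and did not pass the test (adjusted p = 0.14). Gpnmb, a glycoprotein gene of lipid-associated macrophages, was 7.98-fold higher (3.00 ± 0.28, SE, 11 of 11, adjusted p = 4.9e-08). Ccl8 was 15.4-fold higher (3.95 ± 0.25), Mmp12 15.3-fold (3.94 ± 0.30) and the protease gene Ctsk 13.3-fold (3.73 ± 0.41). Ifitm6 had a log2 fold change of -4.93 ± 0.23, S100a4 of -4.76 ± 0.25 and Ccr2, the receptor by which monocytes leave the bone marrow, of -2.48 ± 0.13, each lower in 11 of 11 samples. Of 7641 genes 3779 passed, 1720 higher and 2059 lower in the PD-L1-high gate.

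Interferon response genes were lower in 19 of 19 (19 adjusted over the list alone, median -1.61), including Gbp2 (-1.67), Ifi204 (-1.61) and Usp18 (-1.52). Monocyte genes were lower in 11 of 13 (11, median -2.45), with Vcan at -4.86 and Plac8 at -3.34. Disease-associated microglia genes were higher in 13 of 17 (13 adjusted over the list alone, median 0.97), Spp1 by 2.58, Cd63 by 2.34 and Trem2 by 1.23. Complement genes were higher in 9 of 15 and lower in 2 (9 and 2), and lysosome and lipid genes higher in 8 of 14 and lower in 2 (8 and 2). Homeostatic microglia genes were lower in 9 of 13 with 1 higher (9 and 1), among them Crybb1 (-1.67) and Gpr34 (-1.36), MHC class I genes lower in 7 of 12 with 3 higher (7 and 3), and chemokines and cytokines lower in 10 of 19 with 3 higher (10 and 3). With an estimated correlation these 8 calls were lost (adjusted p = 0.066 to 0.50). The call that held was for dissociation-induced genes, lower in 12 of 15 with 1 higher (14 and 1 adjusted over the list alone, adjusted p = 0.044 with an estimated correlation), including Atf3 (-0.99), Ier2 (-0.79) and Btg2 (-0.68).

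Monocyte-like clusters made up a median over samples of 6.82% of the PD-L1-high and 75.6% of the low gate. Within macrophage-like clusters alone 823 genes passed, with interferon response genes lower in 14 of 19 (median -0.40), dissociation-induced genes in 12 of 15 (median -0.39) and monocyte genes in 8 of 12 (median -1.06). Disease-associated microglia genes were there higher in 10 of 15 and lower in 1 (median 0.36). There MHC class I genes were lower in 1 of 12 (median 0.05). In the PD-L1 gates of the whole class, the 1 lymphocyte or NK gene tested was lower (-3.50). Of 3 oligodendrocyte genes 1 was higher and 2 lower, and of 2 granulocyte genes 1 was higher and 1 lower. The 1 lymphocyte or NK gene tested was higher in the Ly-6C (1.80) and CD74 gates (1.58) of this class. Library size scaling put the median of all genes at 0.13 and moved the split to 2495 higher and 1444 lower, and 2484 genes passed without pool 1.

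**Figure D4:**
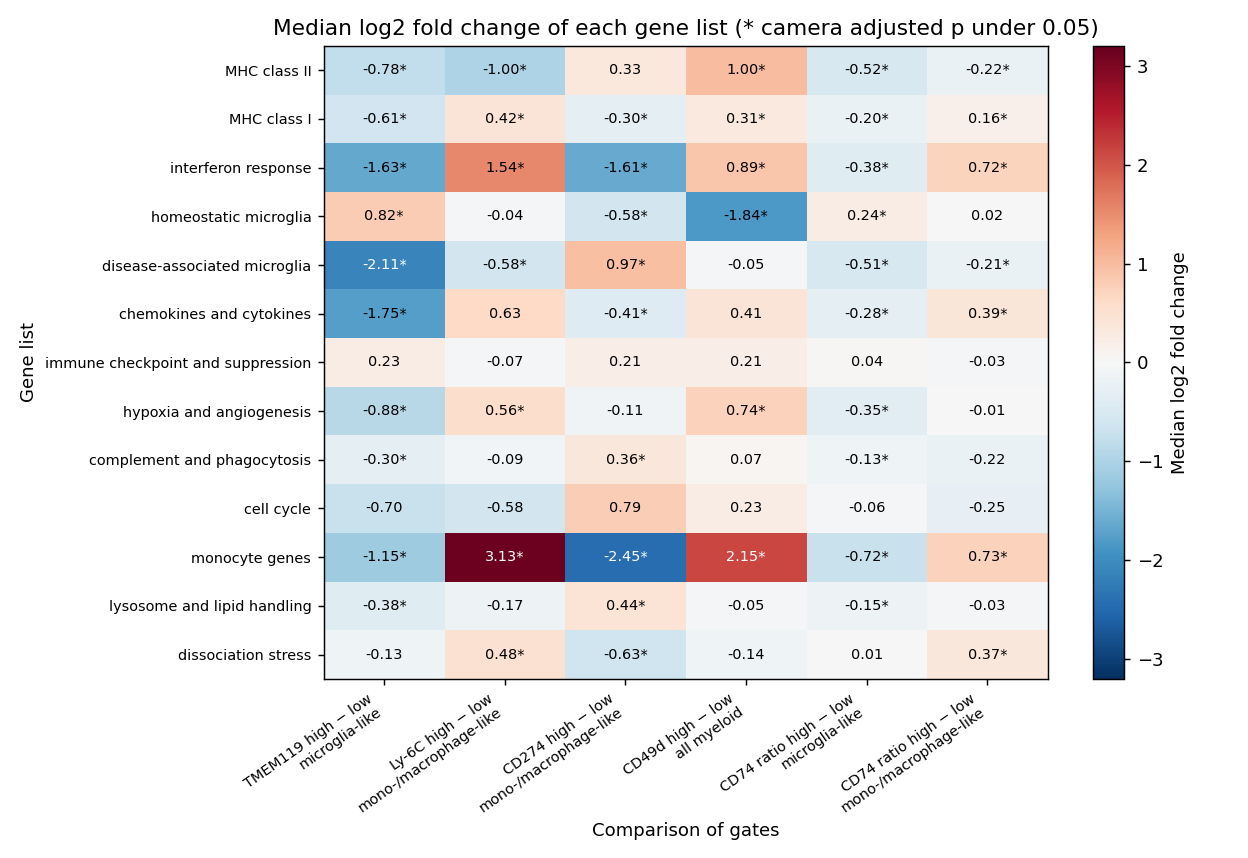
Heat map of the median log2 fold change of tested members for each gene list (vertical axis) in 6 comparisons of protein gates (horizontal axis), with the median printed in each field and a star where camera with a preset correlation gave an adjusted p under 0.05. Interferon response genes stand at -1.63 in the TMEM119 gates, 1.54 in the Ly-6C gates and -1.61 in the CD274 (PD-L1) gates; in the CD74 gates of microglia-like cells they stand at -0.38, a direction that turned to 0.71 with raw-count gates.

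With CD74 protein high relative to the other tags, monocyte- and macrophage-like cells held more interferon-induced and monocyte RNA, and within macrophage-like clusters alone no gene of either list was called higher. Vcan was 6.07-fold higher (log2 fold change 2.60 ± 0.27, SE, 10 of 11 samples, adjusted p = 4.0e-06) and Timp1 5.35-fold (2.42 ± 0.31). The membrane protein genes Tmem176a (1.53 ± 0.12) and Tmem176b (1.39 ± 0.11) were higher in 11 of 11 samples. F7, coagulation factor VII, had a log2 fold change of -0.90 ± 0.11 and Itgax of -0.80 ± 0.12. Cd74 itself was lower by -0.22 ± 0.06 (9 of 11, adjusted p = 0.024), where raw gates gave 0.11 (adjusted p = 0.12) and macrophage-like clusters alone 0.02. Of 7631 genes 1022 passed, 717 higher and 305 lower.

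Interferon response genes were higher in 19 of 19 (19 adjusted over the list alone, median 0.72), with Usp18 at 0.72 and the transcription factor genes Irf7 at 0.54 and Stat2 at 0.55. Monocyte genes were higher in 10 of 13 and lower in 1 (10 and 2), dissociation-induced genes higher in 13 of 15 (14 adjusted over the list alone), with the heat shock gene Hspa1a at 1.45 and Atf3 at 0.54, and MHC class I genes higher in 6 of 12 (8, with 2 lower). MHC class II genes, none of which passed with raw gates (median 0.03), were lower in 4 of 9 (4, median -0.22). H2-Ab1 stood at -0.43 and H2-Aa at -0.38, the latter at 0.02 with raw gates. Disease-associated microglia genes were lower in 6 of 16 with 1 higher (9 and 1), the tetraspanin gene Cd9 by -0.55. These 6 calls were lost with an estimated correlation (adjusted p = 0.099 to 0.39). Chemokines and cytokines, higher in 9 of 18 and lower in 2 (11 and 3), kept theirs (adjusted p = 0.042), Il18 by 1.20, Ccl2 by 0.76 and Ccl9 by 1.42, against Il1a at -0.89. With raw gates interferon response genes were higher in 16 of 19 (median 0.44). Monocyte-like clusters made up a median over samples of 38.0% of the CD74-high and 15.7% of the low gate, with the order reversed under hashtag 5 of pool 3 (7.84% and 15.7%). Within macrophage-like clusters alone 118 genes passed, none of them on the MHC class I or II lists (medians 0.04 and -0.02). There no interferon response gene passed, monocyte genes were lower in 2 of 11 with none higher (median -0.15), chemokines and cytokines were higher in 6 of 18 (median 0.01), Ccl9 standing at -0.04, and dissociation-induced genes were higher in 8 of 15 (median 0.27). The count was 47 without pool 1 (where 14 of 30 named genes, Cd74 at -0.19 among them, no longer passed), 673 without pool 2, 361 with raw gates, 483 with counts summed per pool and 12 with no block, and library size scaling gave 533 higher and 650 lower.

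**Figure D5:**
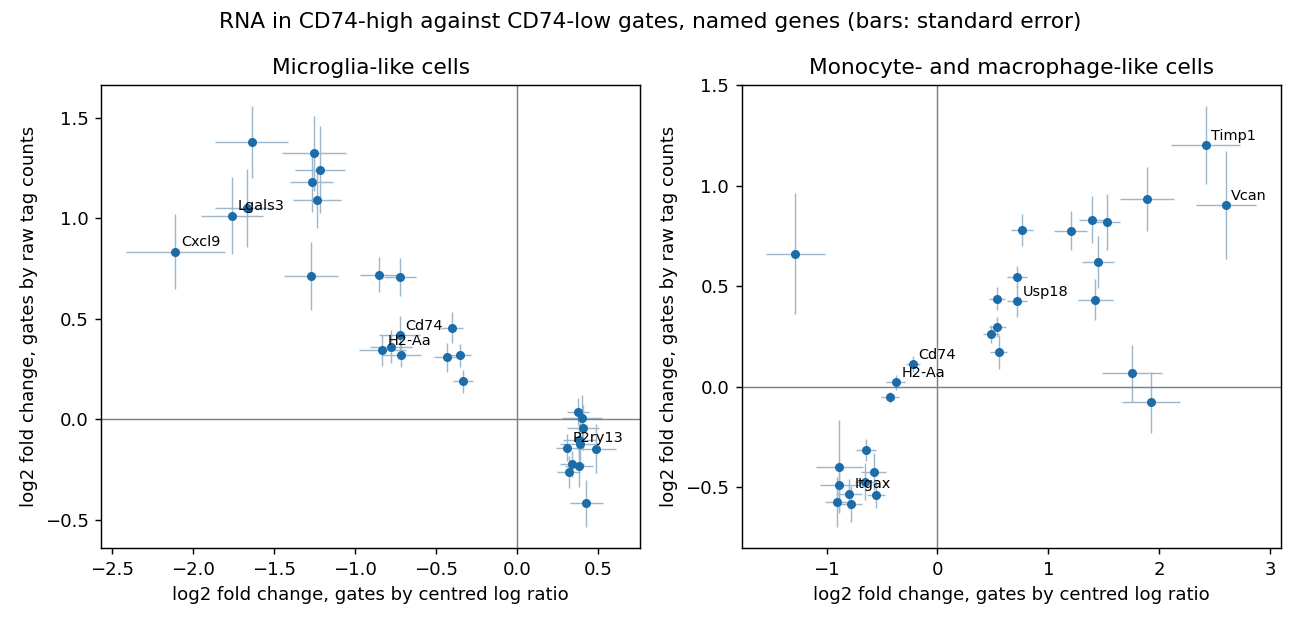
Log2 fold change of the named genes between CD74-high and CD74-low gates, with gates by centred log ratio (horizontal axis) and by raw tag counts (vertical axis), in microglia-like (left) and monocyte- and macrophage-like cells (right). Points are genes and bars standard errors over 16 and 11 hashed samples; Cd74 lies at -0.73 and 0.42 on the left and at -0.22 and 0.11 on the right.

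Whether RNA went with CD74 protein alike in the 2 classes was tested as a difference of their fold changes. Interferon-induced genes and chemokines had the lower fold change in microglia-like cells. Cxcl9 differed by -3.18 ± 0.37 (log2, SE, lower in 9 of 9 samples, adjusted p = 1.4e-07), Gbp2 by -2.05 ± 0.22, Ifitm3 by -1.51 ± 0.13 and Irf7 by -1.25 ± 0.13. The matrix gene Fn1 (fibronectin) differed by -2.69 ± 0.29 and the annexin gene Anxa2 by -2.85 ± 0.35. The kinase gene Sgk1 (0.93 ± 0.15) and the microglial receptor gene Gpr34 (0.79 ± 0.24) differed in the other direction. Of 8700 genes 1190 passed over 9 samples, 233 higher and 957 lower in microglia-like cells. With raw gates 841 of the 1186 genes in both had the opposite sign, and Cxcl9 (0.41), Ifitm3 (0.50), Gbp2 (0.14), Irf7 (0.27), Fn1 (2.18), Anxa2 (1.17) and Gpr34 (-0.88) turned direction.

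All 19 tested interferon response genes were lower (19 adjusted over the list alone, adjusted p = 0.034 with an estimated correlation), and 12 of 19 chemokines and cytokines (13 lower and 1 higher, adjusted p = 0.024), Ccl2 by -1.14 and Cxcl16 by -0.99. The other 8 camera calls were lost with an estimated correlation (adjusted p = 0.059 to 0.27). They were MHC class I, lower in 9 of 12 (10), with the immunoproteasome genes Psmb8 at -0.69 and Psmb10 at -0.65, MHC class II in 2 of 10 (7), hypoxia in 9 of 14 (9), with Pgk1 at -0.96, monocyte genes in 5 of 12 (7), disease-associated microglia genes in 8 of 17 with 2 higher (10 and 2), lysosome and lipid genes in 6 of 15 with 1 higher (7 and 1), dissociation-induced genes in 5 of 15 (6) and homeostatic microglia genes, higher in 5 of 16 (8). The gates of the other class differed in makeup. Its own comparison had 11 samples, of which 9 entered the interaction. Over the 11, the median share of monocyte-like cells was 38.0% in the CD74-high and 15.7% in the low gate. Within macrophage-like clusters of that class, interferon response genes had a median of 0.09 against 0.72 in its own comparison. The interaction was not run within those clusters. With raw gates no interferon response gene was lower and 3 of 19 were higher (median 0.15), and chemokines and cytokines were higher in 7 of 19 and lower in 4 (median 0.41). Raw gates also gave disease-associated microglia genes higher in 14 of 17, homeostatic genes lower in 12 of 16 and dissociation-induced genes lower in 13 of 15 (median -0.73). Library size scaling put the median of all genes at 0.21 and moved the split to 958 higher and 514 lower. The count was 173 without pool 1 (where 15 of 30 named genes no longer passed), 759 without pool 2, 531 with counts summed per pool and 84 with no block.

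Across all myeloid cells, CD49d protein separated cells with RNA of blood-derived myeloid cells from cells with microglial RNA. Itga4, its coding gene, was 5.36-fold higher (log2 fold change 2.42 ± 0.38, SE, 15 of 16 samples, adjusted p = 3.9e-05). Pf4, platelet factor 4, also a marker of border macrophages, was higher by 3.46 ± 0.71 on the log2 scale, the calcium-binding protein gene S100a4 by 3.08 ± 0.42 and the mannose receptor gene Mrc1 by 2.66 ± 0.48. Tmem119 had a log2 fold change of -1.90 ± 0.29, P2ry12 of -2.30 ± 0.33 and Siglech of -2.67 ± 0.38, each lower in 16 of 16 samples. H2-Aa (1.38 ± 0.31), Cd74 (1.19 ± 0.32) and Cd274 (0.93 ± 0.21) were higher, in 15, 16 and 13 of 16. Of 10129 genes 5875 passed, 2867 higher and 3008 lower in the CD49d-high gate, which held a median over samples of 12.1% microglia-like cells against 88.4% in the low gate. The high gates under hashtags 1 and 2 of pools 1 and 2 were 53.3 to 82.4% microglia-like. The low gates under hashtags 3 to 6 of pool 1 were 67.7%, 60.6%, 44.7% and 57.3% microglia-like. Under hashtags 4, 5 and 6 of pool 3 the low gates were 64.5%, 31.3% and 6.22% microglia-like.

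Homeostatic microglia genes were lower in 16 of 16 (16 adjusted over the list alone, median -1.84), with Olfml3 at -1.63 and Cst3 at -1.49. Monocyte genes were higher in 13 of 13 (13, median 2.15), with S100a6 at 2.43, interferon response genes in 19 of 19 (19, median 0.89), with Ifitm3 at 1.80 and Cxcl10 at 1.31, and hypoxia genes in 14 of 14 (14, median 0.74). MHC class I genes were higher in 7 of 12 (7) and MHC class II genes in 7 of 10 with 2 lower (8 and 2). These 6 calls were lost with an estimated correlation (adjusted p = 0.36 to 0.48). Camera did not call disease-associated microglia genes, 6 higher and 7 lower of 17, nor complement genes, 5 higher and 7 lower of 16, checkpoint genes, 6 higher and 4 lower of 11, cell cycle genes, 1 higher and 1 lower of 10, chemokines and cytokines, 10 higher and 4 lower of 19, lysosome and lipid genes, 4 higher and 6 lower of 15, or dissociation-induced genes, 2 higher and 6 lower of 15. Median and mean differed in sign for disease-associated (-0.05 and 0.07), complement (0.07 and -0.20) and lysosome genes (-0.05 and 0.05). Of genes of other cell types, 2 oligodendrocyte genes were higher and 2 lower of 4 (median -0.37, against an upward camera statistic), 1 lymphocyte or NK gene was lower of 2, and 2 granulocyte genes were lower of 5, where raw-count gates gave 4 granulocyte genes higher and 1 lower of 5 (median 4.22). The size of other medians also depended on the gates, raw-count gates giving 5.18 for monocyte, 1.71 for interferon response and 1.70 for hypoxia genes. MHC class I genes were then higher in 11 of 12. Library size scaling put the median of all genes at -0.21 and moved the split to 1855 higher and 4620 lower. Without pool 2, 3165 genes passed, and Ly6c2, 1.66 ± 0.39 with all pools, stood at 0.61 and did not pass.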

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

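The tests of Cd74 with raw-count gates, of Cd74 after thinning and of the mixed barcodes in pool 3 were chosen after the results were seen. The restriction to macrophage-like clusters was added after the data were seen, and its bounds for interferon genes were written before its own result was seen. No sex, tumor or day was given to a sample, so no biological explanation from the study's groups was tested.

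The relation of RNA to CD74 protein differed between the cell classes in 1190 genes, tested as an interaction over 9 samples. Swapping gates or classes within samples gave a count as large in 1 of 30 splits, the real one, the highest other being 776 genes. The smallest share that 30 splits can give is 1 of 30, so chance is argued against only to that degree and is not excluded. The real split was likewise the 1 of 30 with the most genes for the TMEM119 gates (3691, highest other 0), the CD74 gates of microglia-like cells (1018, 0), the CD49d gates (5875, 0), and the CD74 (1022, 903), Ly-6C (3767, 1847) and CD274 gates (3779, 1409) of monocyte- and macrophage-like cells. The latter class had 11 samples, and in each of its comparisons 1 drawn split stood far above the other drawn ones.

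In the CD74 comparison of microglia-like cells, Cd74 RNA was lower where CD74 protein was high relative to the other tags. The centred log ratio sets a tag against the others, so cells with many other tags may fall into the low gate, although the gates also differed in raw CD74, with medians over samples of 11 tags in the high and 3 in the low gate, and by a median of -0.30 on the log2 scale in the other tags. With gates by raw CD74 counts the log2 fold change of Cd74 was 0.42 (SE 0.098), the opposite direction, as this explanation needs, although that value was known when the test was chosen and raw gates also pick cells with more tags of every kind. A difference in RNA depth between gates is argued against by thinning, after which Cd74 stood at -0.77 (SE 0.12). The count of 1190 rests on the same scale and on gates of the other class that differ in their share of monocyte-like cells. Medians of that share were 38.0% and 15.7% over 11 samples, not all of which entered the interaction. Whether any of the count reflects CD74 protein itself stays open.

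In pool 3, 80.2% of barcodes without a majority hashtag held both P2ry12 and Ly6c2 RNA, a signal in barcodes that mostly entered no comparison. Free RNA of the pool in most droplets could account for this, since the median chi-square per degree of freedom of 1.14 left little difference between barcodes beyond counting noise. Pairs of cells in 1 droplet are argued against by the 2 highest hashtags holding 56.8% of hashtag UMIs in the median barcode, short of the 80% set for pairs. Intact cells with too little hashtag antibody are argued against by the spread of their RNA, 14.1% of that of barcodes with a majority hashtag.

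Interferon response genes were lower in the CD274-high gate, which also held fewer monocyte-like cells. If the gate only separated monocyte-like from macrophage-like clusters, the median of the list within macrophage-like clusters should lie near 0. It lay at -0.40, with an SE of 0.104 taken over the 19 genes of the list as if independent, not over samples. This is between the bounds written before that value was seen, so the median decides neither way. The bounds were within 0.3 of 0 for a mere separation and below -0.5 by more than 2 such standard errors for a difference of another kind. Of the 19 genes, 14 were still lower past the edgeR test there and 0 higher. These counts argue against a mere separation of the clusters as the whole account. The part played by cluster makeup in the median of -1.61 of the whole class was not measured. Dissociation-induced genes were lower within macrophage-like clusters too (median -0.39, SE over genes 0.071), and a difference in handling was not tested.

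The CCR2 tag, measured in pools 2 and 3 only and used in no comparison, had a median of 75 UMIs on macrophage-like and 10 on microglia-like cells of pool 2, and of 88 and 14 in pool 3. Border-associated macrophage-like cells had 61.5 and 79 in these pools and unnamed cells of pool 3 had 66, and on raw counts 9 of the 10 shared proteins were higher on monocyte- and macrophage-like than on microglia-like cells.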

How the results depend on the processing

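Tests restricted to macrophage-like clusters, with log2 raw tag counts of proteins or with 1 CD49d level per pool were chosen after the data were seen. Comparisons of sex, tumor and day, with their alternatives, were not run, and gates at the median do not apply to CD49d. DESeq2 left 210 of 210 named genes and 7 of 7 counts of genes with the same direction and call or within 1.5 times. Library size scaling changed the call of 2 named genes and turned none, and 1 CD49d level per pool gave 6039 genes against 5875 and left all 30 named genes as they were.

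Gates by raw tag counts turned 57 named genes, all in CD74 comparisons, and left 141 with direction and call. In microglia-like cells the log2 fold changes became -0.14 for Serpinf1, -0.42 for Sox4, -0.040 for Tmem144, -0.12 for Paxbp1, -0.10 for Agmo, -0.23 for Sult1a1, -0.22 for Selplg, -0.14 for P2ry13 and -0.26 for Slc2a5. They became 0.83 for Cxcl9, 1.01 for Lgals3, 1.05 for Lgals1, 1.38 for Fabp5, 1.18 for Cd72, 1.32 for Vim, 1.09 for Cst7, 1.24 for Lilrb4a, 0.42 for Cd74, 0.72 for Gbp2, 0.71 for Ifitm3, 0.46 for Bst2, 0.36 for H2-Eb1, 0.32 for H2-Ab1, 0.34 for H2-Aa, 0.31 for H2-Q7, 0.32 for Psmb8, 0.19 for Psmb9 and 0.71 for Cd36. In the interaction the values became -0.090 for Serpine2, -0.10 for Nav2, -0.13 for Clec4a2, -0.50 for Sparc, -0.88 for Gpr34 and -0.33 for Golm1. They became 0.41 for Cxcl9, 1.80 for Slpi, 1.17 for Anxa2, 0.61 for Ifi203, 1.26 for AA467197, 2.18 for Fn1, 1.31 for Xdh, 0.53 for Ifi205, 0.34 for Cd74, 0.50 for Ifitm3, 0.27 for Irf7, 0.14 for Gbp2, 0.21 for Psmb8, 0.017 for Psmb10, 0.71 for Cxcl16, 0.061 for Ms4a4c, 0.82 for S100a6, 0.33 for Pgk1 and 0.18 for Hif1a. In monocyte- and macrophage-like cells Ifitm6 became -0.077, Saa3 0.66, Cd74 0.11 and H2-Aa 0.023. Raw gates gave 361 genes for CD74 and 2433 for Ly-6C in that class. The cause was not tested beyond the test of Cd74 in microglia-like cells.

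Restriction to macrophage-like clusters turned Ccl9 (-0.037) and Cd74 (0.021) in the CD74 comparison, and gave 118 genes and 3 lists there, 1759 genes for Ly-6C and 823 for CD274, from fewer cells. Among proteins, log2 raw tag counts turned CD11b (1.26) and CD74 (1.92), and log2 counts per 1000 tags turned Gr-1 (-0.26), PD-L1 (-0.026), MHC class II (-0.53) and CD52 (-0.044), with 5 proteins past the test.

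Without the block for the hashed sample, edgeR called 1 gene for CD74 in microglia-like cells (740 at an unadjusted p under 0.05), 12 in the other class (986) and 84 in the interaction (1275), and 83 named genes lost their call. With counts summed per pool and the pool as block the counts were 512, 483 and 531. With the pool as the pair 0 of 10 proteins passed, since the smallest exact p that 3 pairs allow is 0.25.

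Leaving out 1 pool gave 89 to 1089 genes for CD74 and 2063 to 3567 for TMEM119 in microglia-like cells. It gave 47 to 1143 for CD74, 2608 to 3767 for Ly-6C and 2484 to 3696 for CD274 in the other class, 3165 to 6010 for CD49d and 173 to 1243 for the interaction. Each such run has fewer samples. Called lists numbered 9 to 9 and 9 to 10 for CD74 and TMEM119 in microglia-like cells, 6 to 8, 6 to 8 and 7 to 9 for CD74, Ly-6C and CD274, 6 to 7 for CD49d and 9 to 10 for the interaction, and 8 to 9 proteins passed.

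Thinning to 2000 UMIs, which removes counts, gave 422 and 1917 genes for CD74 and TMEM119 in microglia-like cells, 583, 1684 and 1695 for CD74, Ly-6C and CD274, and 626 for the interaction. For CD74 in microglia-like cells a 5% mitochondrial limit gave 632 genes, the Scrublet limit 533 and Leiden resolutions of 0.5 and 2 gave 610 and 609, and the cause was not tested. Resolution 2 left 5 called lists for CD274. With an estimated correlation camera called 0 lists for CD74 and TMEM119 in microglia-like cells, Ly-6C and CD49d (7, 4, 3 and 1 at an unadjusted p under 0.05), 1 each for CD74 and CD274 in the other class, and 2 for the interaction. In the interaction, 47.8% of 2-fold changes simulated at the fixed dispersion were called.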

Other observations

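The values here were picked after the data were seen, and no test was run on them.

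Lymphoid and dendritic cells made up part of the CD11b+ sort. NK cell-like cells, led by the cytotoxic genes Gzma, Gzmb, Prf1 and Nkg7, numbered 647 in all. In pool 1 NK cell-like cells were 0% and 0.0456% of cells under hashtags 1 and 2 and 1.54%, 8.78%, 4.18% and 4.95% under hashtags 3 to 6. In pool 2 NK cell-like cells were 0.162% and 0.347%, then 4.81%, 2.94%, 3.25% and 2.36%, and in pool 3 they were 0% and 0%, then 0.341%, 0.494%, 4.98% and 6.28%. Conventional dendritic cell-like cells (551), with the chemokine gene Ccl17 and the lectin genes Mgl2 and Clec10a in front, reached 5.36% of a sample, and migratory ones (226), with the lymph node homing receptor gene Ccr7 and Ccl22, reached 3.57%. T cell-like cells (68) expressed Icos, Ctla4 and Tnfrsf4, which encode regulators of T cell activation. Smaller clusters held border-associated macrophage-like cells with Cd163, Lyve1 and Mrc1 (119), choroid plexus-like cells with Ttr (152), neutrophil-like cells with Ngp and Camp (62), B cell-like cells with Cd79a (29) and astrocyte-like cells with Slc1a2 (11). Proliferating cells (384), led by Top2a and Birc5, reached 3.76% of a sample.

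Of the monocyte- and macrophage-like clusters, 1 was led by the inflammatory genes Nos2, Inhba and Cxcl2, 1 by Gpnmb, Fabp5 and Apoe, genes of lipid handling, 1 by the interferon-induced genes Rsad2, Ifit1 and Isg20, and 1 by Ace, Ear2, Treml4 and Spn, genes of patrolling monocytes.

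Xist, the RNA that silences an X chromosome in females, fell into separate ranges between hashtags. In pool 1 it stood at 1374, 4.78, 669, 2.04, 485 and 2.46 CPM under hashtags 1 to 6, in pool 2 at 2096, 8.76, 916, 4.88, 746 and 3.51 CPM, and in pool 3 at 1885, 30.3, 1298, 37.9, 609 and 17.7 CPM. The summed Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty stood at 1.77, 199, 0.744, 170, 1.002 and 164 CPM in pool 1, at 2.65, 239, 2.27, 175, 2.09 and 180.2 CPM in pool 2, and at 0.972, 195, 5.85, 172, 3.08 and 170.0 CPM in pool 3. Unnamed cells were left out of these values, so that hashtag 4 of pool 3 is given over 371 of 3241 cells. In each pool Xist was high and the Y-linked genes were low under hashtags 1, 3 and 5, and the reverse held under hashtags 2, 4 and 6. Sex can thus be read from these values, whereas tumor and day cannot. No sample was given a sex from them and no comparison of sex was run, because the plan required hashtags named in the files.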
